A study of Mus musculus with 6 samples.

How the data were processed

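Polyadenylated RNA of mouse muscle stem cells was sequenced in 6 libraries, 3 wild type (WT) and 3 with a Pnpla2 knockout (PKO). Groups and replicate numbers were taken from the sample titles. One table of the whole series holds all values, with its columns named by genotype and number, and no column of another sample was present. The title of the deposited sheet abbreviates the groups differently from the sample titles, for a reason not given, so columns were assigned by their own names only. Per the submitters' processing notes and the series text, reads of 150 bp were sequenced in pairs, filtered for adapters and quality, mapped with TopHat2 to the mouse genome GRCm38 (mm10), and counted per gene with HTSeq 0.6.1. The annotation version and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes, and of near-identical copies, cannot be told apart.

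The deposited read counts are whole numbers per gene and library, and all tests started from them. The table also holds FPKM values, which the authors computed from the counts and a gene length; recomputing them implied library totals at most 1848 reads above the listed counts. A further deposited set is a normalized signal, the counts divided by one factor per library (the factor was constant within a library to a relative spread of 9.8e-10). The authors' log2 fold change and p-value columns come from DESeq2 or edgeR, per the series text, which names both. They were used only for values attributed to the authors' deposited table. FPKM and normalized signal were not used further. The table lists 20588 genes, all with at least 1 count, of which 16380 are protein coding. There are 18 symbols that stand for several gene IDs (37 genes, kept apart by ID), and 25 symbols had been turned into dates. Of the IDs, 20393 are in GENCODE M21 and 14027 have the same start and end there; coordinates are given as in the deposited table.

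Total counts ran from 15580176 to 18839151 per library. At that depth, counting error is small beside the spread between libraries for all but the lowest genes; ratios and floors (3 counts, over the group) cover counting error only. The mitochondrial share of counts was 1.75% to 2.49%.

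The main test was edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr (14025), TMM scaling, a robust quasi-likelihood fit with genotype as the only term, and Benjamini-Hochberg adjusted p under 0.05. Levels are CPM (counts scaled to the library size) with TMM factors, given as mean ± SD over 3 libraries. Log2 fold changes are PKO over WT, with the standard error derived from the fitted value and its F statistic; log2 CPM values used a prior count of 2. Adjusted p-values named without a tool come from this test. DESeq2 1.42.0 (Wald test, unshrunken fold changes, independent filtering optimised for the 0.05 threshold) and limma-voom (limma 3.58.1) were alternatives. A single value, that of Pnpla2, was tested with an exact permutation test.

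The 31 gene lists (819 entries, 790 of them in the table under the current or an older symbol) were fixed before the data were examined, as were the main test, the named-gene rule and most alternatives. They cover lipid droplets, triglyceride synthesis, fatty acid uptake, fatty acid oxidation, PPAR targets, lipogenesis, cholesterol synthesis, oxidative phosphorylation, mitochondrial mRNA, the tricarboxylic acid cycle, glycolysis, quiescence, myogenic commitment, differentiation and fusion, sarcomere, cell cycle, p53 targets, unfolded protein response, NRF2 targets, inflammation, interferon response, autophagy and lysosome, extracellular matrix, Notch, and markers of stromal, adipocyte, endothelial, leukocyte, pericyte, Schwann and erythroid cells. A list needed 3 tested genes, which left 30. Each was tested with camera on limma-voom values with the preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry stood beside it. Camera called 19 lists, 9 higher and 10 lower. None of the 19 held with an estimated correlation (smallest adjusted p 0.494), and fry called 0 (smallest adjusted p 0.247), with 15 lists at a mixed p under 0.05 without adjustment. Counts adjusted over the list alone use edgeR's p-values of the list's genes.

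Named genes followed a rule with these parts: Pnpla2; the 10 genes with the highest and the 10 with the lowest fold change among edgeR calls with a mean of at least 1 CPM, non-overlapping groups and a protein-coding symbol (0 genes met this); up to 4 members with the smallest p of each list other than cell type markers; Pax7, Myf5, Myod1, Myog, Mymk, Mki67, Plin2, Cpt1a and Pdk4; and the 3 markers of each other cell type with the highest mean CPM. The text names mostly the leading 2 members of a list. Applying the second part to the DESeq2 calls was decided after seeing the data.

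Alternatives fixed beforehand were RLE and upper-quartile factors, library size only, no filter, a mean of at least 1 CPM, DESeq2, limma-voom, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were sex (read from Xist and Y-linked counts) as a term, number 1 against numbers 2 and 3 as a term, leaving out WT 1 and PKO 1 or PKO 2 and PKO 3, no robust fit, and the DESeq2 counts under these designs. Tests were first run on simulated data drawn from the real means, library sizes and dispersions, with independent genes and 200 genes changed by known folds. For 3 against 3 libraries a simulated list shifted 2-fold was called by camera with either correlation and by fry. For 2 against 2 it was called by camera with the preset correlation and by fry, but not with an estimated correlation (adjusted p = 0.119). Of 30 unchanged lists 0 were called in either size. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.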

Results

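RNA-seq libraries were made from mouse muscle stem cells (satellite cells, the resident progenitors of skeletal muscle) that carried a knockout of Pnpla2 or were wild type. Pnpla2 encodes adipose triglyceride lipase, the enzyme that starts the breakdown of triglyceride stored in lipid droplets. Per the labels and the series text, the cells were sorted from hind limb muscles of C57BL/6NJ mice aged 2 months. They were then grown for 7 days and kept for a further 16 h in medium with 2% horse serum, a low-serum step that starts myogenic differentiation. There were 3 wild-type libraries (WT 1, WT 2 and WT 3) and 3 knockout libraries (named PKO in the labels: PKO 1, PKO 2 and PKO 3). The total count per library was 17322616, 15580176 and 18651348 in WT 1 to WT 3, and 18706598, 17237752 and 18839151 in PKO 1 to PKO 3. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values below measure the spread between these libraries, which may be partly technical. The comparison asks how loss of the lipase changes the transcriptome of muscle stem cells after this culture.

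The PKO libraries had less Pnpla2 mRNA, more mRNA of the lipid droplet coat gene Plin2, and higher levels of antioxidant, lysosomal, inflammatory and extracellular matrix genes than the WT libraries. Markers of stromal cells (fibro-adipogenic progenitors and fibroblasts) were higher too. Their list median relative to the WT mean was 0.82, 4.20 and 3.44 in PKO 1 to PKO 3, so these differences cannot be placed in the myogenic cells alone. Cell cycle, sarcomere, tricarboxylic acid cycle and cholesterol synthesis genes were lower, with WT 1 below each PKO library in the cell cycle genes. In list medians, PKO 1 lay above WT 2 and WT 3 for sarcomere genes, and WT 1 lay below PKO 1 for cholesterol synthesis genes. None of these list differences passed camera with an estimated correlation (smallest adjusted p = 0.494). The size of most of these differences varied between libraries of one group: PKO 2 and PKO 3 were far from WT, PKO 1 lay between, and WT 1 resembled PKO 1 more than the other WT libraries. No single gene passed an adjusted p threshold of 0.05 over all 14025 genes tested with edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 1426 genes were higher and 891 lower in PKO, and DESeq2 called 766 genes higher and 151 lower at its adjusted p threshold. Splits of the libraries that mixed the genotypes gave up to 1690 genes at that unadjusted p and up to 342 DESeq2 calls. The real split gave 2317 and 917.

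Pnpla2 itself (ENSMUSG00000025509, chromosome 7, 141455198 to 141460743 on the plus strand, GRCm38) was at 21.1, 38.5 and 33.7 CPM (counts scaled to the library size) in WT 1 to WT 3. It was at 8.5, 16.0 and 15.5 CPM in PKO 1 to PKO 3, so that every PKO library lay below every WT library. The mean was 31.1 ± 8.96 CPM in WT and 13.3 ± 4.19 CPM in PKO (SD, n = 3 each), and the PKO mean was 42.8% of the WT mean. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries can give. The log2 fold change was -1.22 ± 0.32 (SE), with adjusted p = 0.191 in edgeR and 0.00796 in DESeq2. Over the alternatives its adjusted p ran from 0.00734, with WT 1 and PKO 1 left out, to 0.924, with PKO 2 and PKO 3 left out, where a single PKO library remained and the log2 fold change was -1.88. It was 0.0355 without WT 1. The counts cover the whole gene and the labels do not say which part was deleted, so the remaining reads can come from transcript outside the deleted part. Neither this source nor any other was tested. Pnpla2 was higher in PKO 2 and PKO 3 than in PKO 1. Stromal marker medians relative to the WT mean were likewise higher there, at 4.20 and 3.44 against 0.82 in PKO 1.

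**Figure D1:**
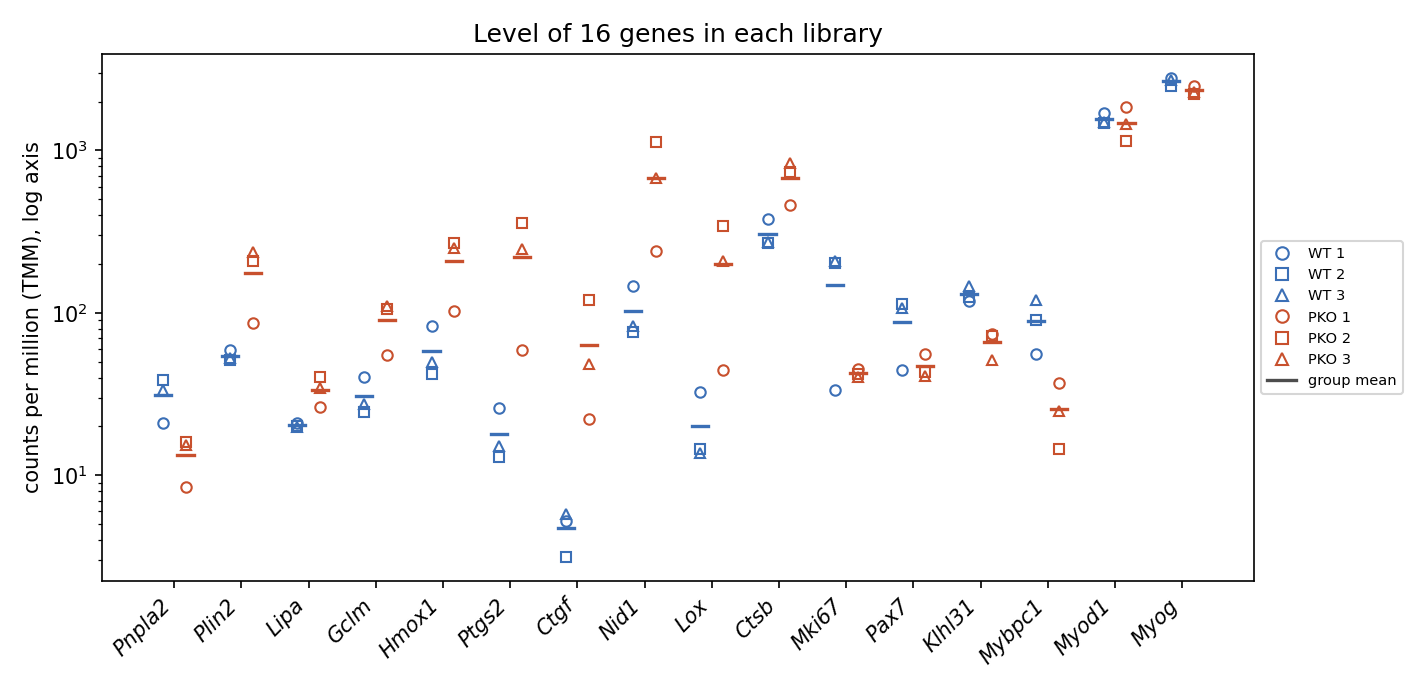
CPM of 16 genes in each library on a log axis, with WT libraries in blue, PKO libraries in red, a symbol for each replicate number, and a bar at each group mean (n = 3). Pnpla2 lies lower in each PKO library than in any WT library, Plin2 and Ctgf lie higher in each, and in WT 1 Pax7 lies among the PKO libraries and Mki67 below them.

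Genes of the lipid droplet and of lipolysis were higher as a list in PKO, led by Plin2 and Lipa. The list median relative to the WT mean was 0.079 in WT 1, above PKO 2 at 0.067, and 0.149 and 0.261 in PKO 1 and PKO 3. Plin2, which coats lipid droplets, was at 54.7 ± 4.16 CPM in WT and 177 ± 80.1 CPM in PKO, a 3.24-fold difference (log2 1.70 ± 0.35 SE). Its adjusted p was 0.179 over all genes with edgeR and 0.000179 with DESeq2. Its level in PKO 1 was 86.3 CPM, against 209 and 237 CPM in PKO 2 and PKO 3. Lipa, the lysosomal acid lipase, was 1.66-fold higher (edgeR adjusted p = 0.185, DESeq2 adjusted p = 0.0232). These 2 of 21 genes rose when edgeR's p was adjusted over the list alone, 0 rose over all genes tested, 3 rose with DESeq2, and the list median was only 0.10 on the log2 scale. The list passed camera (adjusted p = 0.04), but not with an estimated correlation (adjusted p = 0.494 with an estimated correlation). Without WT 1, WT 2, WT 3, PKO 1 or PKO 3 the camera adjusted p was 0.0592, 0.127, 0.0895, 0.068 and 0.148.

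For triglyceride synthesis (15 genes) the median log2 fold change was -0.04 and camera's adjusted p 0.303, with Agpat3 at -0.49 ± 0.14 and Gpam at -0.66 ± 0.25. Fatty acid uptake and activation (16 genes) had a median of -0.03 (camera adjusted p = 0.949), a list whose mean was slightly above 0 at 0.01. Within it Lrp1, an endocytic receptor, was 2.66-fold higher, with an edgeR adjusted p of 0.191. Mitochondrial fatty acid oxidation had 17 of 23 genes lower (median -0.18, camera adjusted p = 0.0765). Without PKO 1 or PKO 3 that p was 0.0381 and 0.00926, and without WT 1 or PKO 2 it was 0.1725 and 0.662. The list median relative to the WT mean was -0.02, -0.36 and -0.10 in PKO 1 to PKO 3, lowest in PKO 2. Hadhb, part of the trifunctional protein of beta-oxidation, was lower in each PKO library than in any WT library (log2 -0.43 ± 0.13), while the carnitine palmitoyltransferase genes Cpt1a (0.40 ± 0.13) and Cpt1c (0.43 ± 0.14) were higher in each. PPAR target genes had 12 of 21 members higher (median 0.19, camera adjusted p = 0.332). Plin2 was the 1 member that rose adjusted over the list alone, Angptl4 was at 2.63 times the WT level (edgeR adjusted p = 0.191, DESeq2 0.00522), and Pdk4 differed little (0.23 ± 0.41). In de novo lipogenesis and desaturation 14 of 17 genes were lower (median -0.33, camera adjusted p = 0.04, adjusted p = 0.494 with an estimated correlation). That call ended without WT 2, WT 3, PKO 1 or PKO 3 (0.127, 0.11, 0.108 and 0.109). The list median relative to the WT mean was -0.38 in WT 1 and -0.24, -0.15 and -0.40 in PKO 1 to PKO 3, so that WT 1 lay below PKO 1 and PKO 2. Its 4 members with the smallest p went both ways. The malic enzyme gene Me1 was 1.47-fold and the citrate carrier gene Slc25a1 1.87-fold higher. Scd2 and Fads3 were at 0.60 and 0.81 times the WT level, each lower in every PKO library than in any WT library.

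Tricarboxylic acid cycle and cholesterol synthesis genes were modestly lower in PKO, and the subunits of oxidative phosphorylation were lower in PKO 2 but not in PKO 3. All 18 tricarboxylic acid cycle genes had a negative log2 fold change (median -0.31, camera adjusted p = 1.34e-06, adjusted p = 0.494 with an estimated correlation). Its median relative to the WT mean was -0.18, -0.49 and -0.31 in PKO 1 to PKO 3, lowest in PKO 2 and PKO 3, where stromal markers were also high. Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, was at 231 ± 59.7 CPM in WT and 122 ± 19.4 CPM in PKO (edgeR adjusted p = 0.185, DESeq2 0.00796). Dlat, a pyruvate dehydrogenase subunit, was at -0.44 ± 0.13. Cholesterol synthesis had 22 of 23 genes lower (median -0.41, camera adjusted p = 1.01e-06, adjusted p = 0.494 with an estimated correlation), among them Idi1 (-0.68 ± 0.25), with WT 1 at a list median of -0.32 relative to the WT mean and so within the range of the PKO libraries. In neither list did a member pass adjusted over the list alone, and with DESeq2 1 tricarboxylic acid cycle gene (Idh2) and 0 cholesterol synthesis genes fell. Nuclear genes of oxidative phosphorylation subunits were lower in 62 of 77 cases by a median of -0.12 (camera adjusted p = 0.000339, adjusted p = 0.604 with an estimated correlation). Relative to the WT mean the list median was -0.05, -0.41 and 0.09 in PKO 1 to PKO 3, against -0.06 to 0.08 in the WT libraries. Atp5a1 was at -0.40 ± 0.15 and Ndufs1 at -0.35 ± 0.14. This list rested on few libraries: its camera adjusted p was 0.154 without WT 1 and 0.853 without PKO 2. Mitochondrially encoded mRNA were lower in 11 of 12 cases (median -0.20, camera adjusted p = 0.04, adjusted p = 0.575 with an estimated correlation), with 0.221 without WT 1 and 0.673 without PKO 2. Their list median was 0.00, -0.46 and -0.08 in PKO 1 to PKO 3. mt-Cytb was at -0.32 ± 0.20 and mt-Nd4l at -0.41 ± 0.32. Glycolysis had 19 of 23 genes lower (median -0.24, camera adjusted p = 0.04, adjusted p = 0.494 with an estimated correlation), although Eno2 and Hk2 were 2.38-fold and 1.79-fold higher (log2 1.25 for Eno2, and 1.89 without WT 1). The list median was -0.20 in WT 1 and -0.22, -0.42 and -0.13 in PKO 1 to PKO 3. Its camera adjusted p without WT 2, WT 3, PKO 1 or PKO 2 was 0.0549, 0.104, 0.123 and 0.173.

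Myod1 and Myog differed little between genotypes, while Pax7, Myf5 and later muscle genes were lower in PKO, though neither Pax7 nor Myf5 passed edgeR or DESeq2. Myod1 was at 1557 ± 127 CPM in WT and 1484 ± 353 CPM in PKO, and Myog at 2679 ± 152 and 2345 ± 139 CPM. The fusion gene Mymk (listed under its older symbol Tmem8c) was at 916 ± 261 and 822 ± 156 CPM, and the direction of its small difference and of that of Myod1 changed with the libraries used. Pax7, the satellite cell transcription factor, was at 44.5, 114 and 107 CPM in WT 1 to WT 3 and at 56.2, 43.6 and 41.1 CPM in PKO 1 to PKO 3 (edgeR adjusted p = 0.269). Myf5 was at 50.7 ± 19.2 CPM in WT and 26.0 ± 15.6 CPM in PKO (adjusted p = 0.381). In WT 1 it was at 28.56 CPM, below PKO 1 at 40.99 CPM and close to PKO 3 at 27.15 CPM. The commitment and myoblast list had 14 of 18 genes lower by a median of -0.12, led by Itga7 (-0.74 ± 0.20), the laminin-binding integrin of muscle, and Eya1 (-0.45 ± 0.14). Its camera adjusted p of 0.0199 became 0.125, 0.0956 and 0.148 without WT 1, PKO 2 and PKO 3, and was 0.494 with an estimated correlation. Early differentiation and fusion genes were lower in 22 of 27 cases (median -0.37, camera adjusted p = 0.000403, adjusted p = 0.494 with an estimated correlation). Klhl31, a kelch gene of muscle differentiation, fell adjusted over the list alone, from 130 ± 14.2 to 65.9 ± 12.9 CPM, and the fusion gene Mymx (listed as Gm7325) was at -0.56 ± 0.16. Sarcomere genes were lower in 41 of 48 cases (median -0.47, camera adjusted p = 1.34e-06, adjusted p = 0.494 with an estimated correlation). Relative to the WT mean the sarcomere median was -0.04, -0.63 and -0.60 in PKO 1 to PKO 3 and 0.41, -0.28 and -0.13 in WT 1 to WT 3. The commitment median was 0.11, -0.38 and -0.46 and the differentiation and fusion median -0.09, -0.35 and -0.40 in PKO 1 to PKO 3, so that the 3 lists were lowest in PKO 2 and PKO 3, the libraries with high stromal markers. Mybpc1, a slow-muscle myosin-binding protein gene, was at 0.29 times the WT level (edgeR adjusted p = 0.179, DESeq2 0.000337) and Tnni2, fast troponin I, at 0.63 times. Without WT 1, whose sarcomere list lay highest of the 6 libraries, the camera adjusted p of these 2 lists was 0.13 and 0.154. Quiescence and self-renewal genes went both ways (14 of 25 higher, camera adjusted p = 0.903). In that list Cd34, which stromal cells also express, was at 5.32 ± 2.05 CPM in WT and 80.3 ± 71.3 CPM in PKO (log2 3.91, and 2.99 without PKO 3), and Fgfr4 was at 0.43 times the WT level. Notch signalling genes also went both ways (7 of 17 higher, camera adjusted p = 0.449), with the ligand gene Jag1 at 1.39 ± 0.39 and the receptor gene Notch3 at -0.86 ± 0.30.

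Cell cycle genes were lower in all 3 PKO libraries and in WT 1 than in WT 2 and WT 3. Of 55 genes 54 had a negative log2 fold change (median -1.13), and the list passed camera with adjusted p = 1.19e-09, lost with an estimated correlation (adjusted p = 0.494 with an estimated correlation). Relative to the WT mean the list median was -1.29 in WT 1, 0.64 in WT 2 and 0.64 in WT 3, and -0.96, -1.01 and -0.62 in PKO 1 to PKO 3. Mki67, a marker of cycling cells, was at 33.7, 204 and 209 CPM in the WT libraries and at 44.9, 42.1 and 40.6 CPM in the PKO libraries (edgeR adjusted p = 0.232, DESeq2 0.0129). E2f2 was at 0.44 times and E2f8 at 0.46 times the WT level, and both lay lower in each PKO library than in any WT library. No member fell adjusted over the list alone or over all genes with edgeR, 12 fell with DESeq2, and 47 of 55 fell with edgeR when WT 1 and PKO 1 were left out, an alternative chosen after seeing the data. p53 targets and cell cycle exit genes had no common direction (9 of 25 higher, camera adjusted p = 0.563), with Perp at 1.66 ± 0.37 and the cell cycle inhibitor gene Cdkn2b at 0.82 ± 0.24.

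Antioxidant genes were higher in PKO, mostly in PKO 2 and PKO 3, the libraries in which stromal markers were also high. Of the 33 tested targets of NRF2, the transcription factor of the oxidative stress response, 31 were higher, 25 rose adjusted over the list alone, 0 over all genes with edgeR, and 19 with DESeq2. The median log2 fold change was 0.92, and camera gave adjusted p = 2.14e-13 (adjusted p = 0.494 with an estimated correlation). Relative to the WT mean the list median was 0.41, 1.08 and 1.17 in PKO 1 to PKO 3. Gclm, a subunit of the enzyme limiting glutathione synthesis, was at 30.9 ± 8.29 CPM in WT and 90.5 ± 30.6 CPM in PKO. Hmox1 (heme oxygenase 1) was 3.55-fold and Srxn1 (sulfiredoxin) 4.99-fold higher, each higher in every PKO library than in any WT library. Gsta1 was 5.31-fold higher at a level of only 2.95 CPM in PKO, and its reads can be shared with related glutathione transferase genes. Autophagy and lysosome genes were higher in 27 of 29 cases (median 0.44, camera adjusted p = 1.94e-08, adjusted p = 0.494 with an estimated correlation). Of these, 8 rose adjusted over the list alone, 0 over all genes with edgeR and 9 with DESeq2. They included Ctsb (cathepsin B, 307 ± 62.2 against 681 ± 195 CPM), Npc2 (2.00-fold) and Gabarapl1 (1.78-fold). The unfolded protein and integrated stress response list did not pass camera (21 of 35 higher, adjusted p = 0.152; 0.0426 without WT 1). Its member Ddit4 rose adjusted over the list alone (log2 0.78 ± 0.16), and Ddit3 was at 1.00 ± 0.26.

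Extracellular matrix and inflammatory genes showed large differences, which were smaller in PKO 1 than in PKO 2 and PKO 3. Of 40 matrix genes 39 were higher, 26 rose adjusted over the list alone, 0 over all genes with edgeR, and 25 with DESeq2 (median 2.29, camera adjusted p = 2.34e-14, adjusted p = 0.494 with an estimated correlation). Ctgf, a matricellular growth factor gene, was at 5.2, 3.1 and 5.8 CPM in WT 1 to WT 3 and at 22.2, 120 and 48.6 CPM in PKO 1 to PKO 3 (log2 3.75 ± 0.64, edgeR adjusted p = 0.179, DESeq2 1.64e-09). Nid1, a basement membrane gene, was 6.67-fold and Mmp14 4.34-fold higher. Without PKO 2 the log2 fold change of Ctgf was 2.91. Loxl2 was at 6.5, 144 and 36.4 CPM in PKO 1 to PKO 3 against a WT mean of 1.05 CPM, with a log2 fold change of 5.86 and of 4.34 without PKO 2. In the inflammatory and NF-kB list 12 of 22 genes rose and 2 fell adjusted over the list alone, 0 over all genes with edgeR, and 13 rose with DESeq2 (median 1.61, camera adjusted p = 0.000176, adjusted p = 0.494 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, was at 18.1 ± 6.95 CPM in WT and 220 ± 150 CPM in PKO, and the chemokine gene Ccl7 was 21.3-fold higher. Saa3 and Icam1 were 8.95-fold and 9.70-fold higher at 3.21 and 2.16 CPM in PKO. Interferon-stimulated genes were higher in 22 of 23 cases (median 1.40, camera adjusted p = 2.82e-06, adjusted p = 0.494 with an estimated correlation). No member passed adjusted over the list alone, and 6 rose with DESeq2. B2m was 2.41-fold higher, and WT 1, at a list median of 0.80, lay above PKO 1, at 0.26.

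Markers of fibro-adipogenic progenitors and fibroblasts, cells that share the muscle interstitium with satellite cells, moved with the matrix and inflammatory genes. Of 15 genes 14 were higher and 13 rose adjusted over the list alone (0 over all genes with edgeR, 9 with DESeq2, median 3.30, camera adjusted p = 9.75e-06, adjusted p = 0.494 with an estimated correlation). Relative to the WT mean the list median was 0.82 in PKO 1, 4.20 in PKO 2 and 3.44 in PKO 3, and between -0.24 and 0.23 in the WT libraries. Its members with the most counts were Gsn (181 ± 63.6 CPM in WT, 311 ± 44.7 CPM in PKO), Lox (20.3 ± 10.7 and 199 ± 150 CPM; log2 3.30, and 2.65 without PKO 2) and Dpep1 (34.9 ± 13.3 and 57.7 ± 2.47 CPM). Endothelial markers were higher in 8 of 9 cases, with 4 that rose adjusted over the list alone (camera adjusted p = 0.0148, 0.0897 without WT 1, adjusted p = 0.494 with an estimated correlation). The log2 fold change of Eng was 1.91, and 0.96 without PKO 2, and Vwf was at 0.72 times the WT level, while Ly6c1 was at 0.28 ± 0.24 CPM in WT and at 0.48, 1.82 and 14.3 CPM in PKO 1 to PKO 3. Only 9 of 15 endothelial, 3 of 15 adipocyte, and 8 of 21 macrophage and leukocyte markers could be tested. The 3 adipocyte markers tested were higher (camera adjusted p = 0.0206, adjusted p = 0.494 with an estimated correlation). Adjusted over these 3 alone, 2 of them rose, Cebpa (1.83-fold) and Pparg (2.34-fold). Relative to the WT mean the adipocyte list median was 0.715 in WT 1, above PKO 2 at 0.56. Car3 was at 89.6 and 191 CPM in WT 1 and PKO 1 and between 7.5 and 85.2 CPM in the other libraries. Macrophage and leukocyte markers were higher in 5 of 8 cases (camera adjusted p = 0.0762). That p was 0.0119, 0.0236, 0.021 and 0.0212 without WT 2, WT 3, PKO 1 and PKO 3. Without WT 1 and PKO 2 it was 0.1725 and 0.16. Lyz2 was at 0.67 ± 0.79 CPM in WT and 7.03 ± 1.77 CPM in PKO (log2 3.34, and 4.97 without WT 3). Laptm5 was at 14.2 ± 7.27 and 8.81 ± 3.59 CPM. Cd53 was at 1.19 ± 1.64 and 7.31 ± 4.05 CPM (log2 2.61, and 4.86 without WT 1). Pericyte and smooth muscle markers went both ways, with 3 that rose and 2 that fell adjusted over the list alone (camera adjusted p = 0.332). Des and Acta2, which myogenic cells express as well, were at -0.20 ± 0.20 and 0.36 ± 0.25. Schwann cell and neural markers went both ways too (3 of 7 higher, median -0.11 but mean 0.09, camera adjusted p = 0.903), with Erbb3 at -0.45 ± 0.27, Cnp at -0.18 ± 0.18 and Pmp22 at 1.47 ± 0.39. Erythroid markers were too low to test: Alas2 had 2 to 11 counts and Slc4a1 at most 1 per library.

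**Figure D2:**
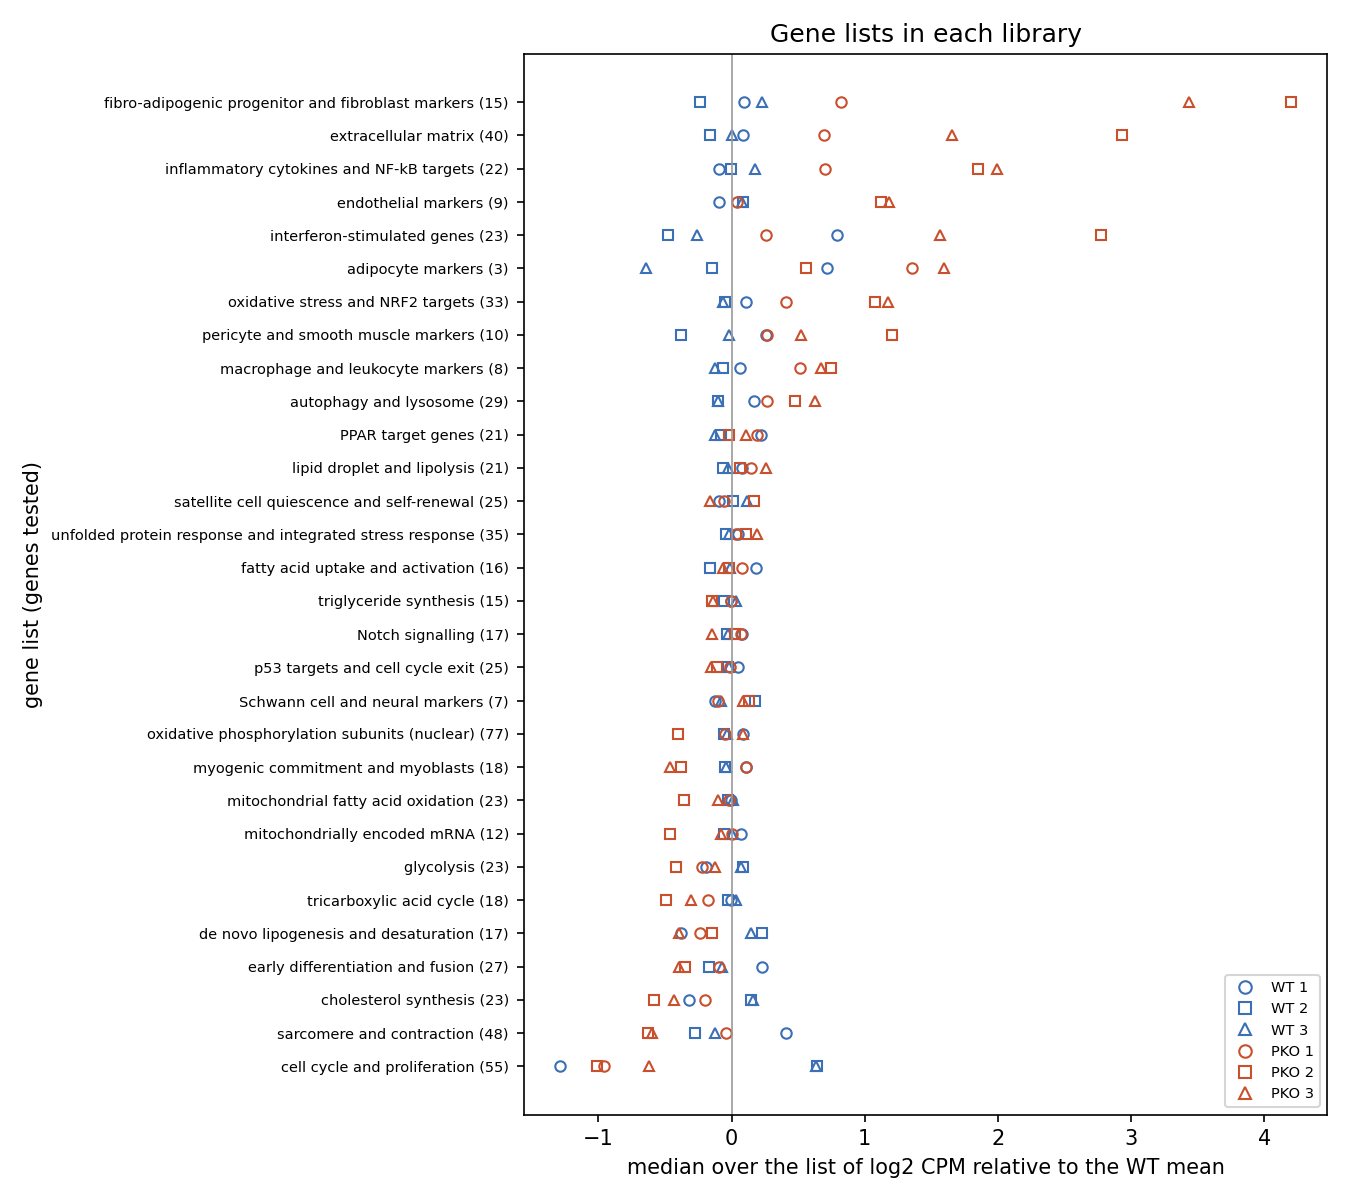
Median over each gene list of log2 CPM relative to the WT mean, for each library, with the number of genes tested in parentheses. The stromal marker and matrix lists lie highest in PKO 2 and PKO 3, and the cell cycle list of WT 1 lies below that of each PKO library.

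Over all genes, libraries of one group differed widely. The first principal component (56.3% of variance) ran from WT 2 and WT 3 through WT 1 and PKO 1 to PKO 2 and PKO 3, and the second (22.9%) set WT 1 and PKO 1 apart from the other 4. Across genes, log2 CPM of WT 1 correlated at 0.984 with PKO 1 and at 0.958 and 0.96 with WT 2 and WT 3. Sex-linked counts differed within both groups: WT 1, WT 2 and PKO 1 had 3151, 3315 and 3971 counts over 4 Y-linked genes, and WT 3, PKO 2 and PKO 3 had 20150, 17122 and 10007 counts of Xist. With sex as a term, chosen after seeing the data, DESeq2 called 318 genes higher and 49 lower, edgeR called 0, and camera called 17 lists. Of the genes tested 1643 had every PKO library above every WT library and 1363 the reverse, together 21.4%. A chance share of 10% holds only as an average over the splits of the libraries into 3 and 3. Genes vary together, so a single split can lie far from that average, and the 21.4% does not by itself set chance aside.

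The edgeR counts depended on the libraries. With none of them left out, edgeR called 0 genes and its smallest adjusted p was 0.179. It called 517 genes higher and 483 lower without WT 1, 659 and 78 without PKO 1, and 0 without any one of the other 4. With WT 1 and PKO 1 both left out, chosen after seeing the data, it called 1461 and 805. For 2 against 2 simulated libraries, 15.5% of edgeR's calls and 17.4% of those of DESeq2 were among unchanged genes. These shares leave out the truly changed genes of the simulated shifted list, whose calls would lower them. DESeq2 called 766 higher and 151 lower, of which 646 and 83 differed at least 2-fold, and limma-voom called 0 (1328 and 780 at an unadjusted p under 0.05). The DESeq2 counts were 1434 and 918 without WT 1, 275 and 20 without WT 2, 261 and 13 without WT 3, 1158 and 372 without PKO 1, 234 and 58 without PKO 2, and 243 and 32 without PKO 3. On simulated counts for 3 against 3 libraries (14025 genes), edgeR recovered 28% of genes changed 2-fold, 86% at 4-fold and 98% at 8-fold. DESeq2 recovered 50%, 92% and 98%. Again without the shifted list, 26.3% of its calls were among unchanged genes, against 6.1% for edgeR. The authors' deposited table lists 705 genes higher and 152 lower at an adjusted p under 0.05, of which 701 and 149 were also called by DESeq2 here. Some DESeq2 calls named in the text are not called in that table. Its adjusted p was 0.137 for Mki67, 0.229 for Medag and 0.0898 for Il6.

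**Figure D3:**
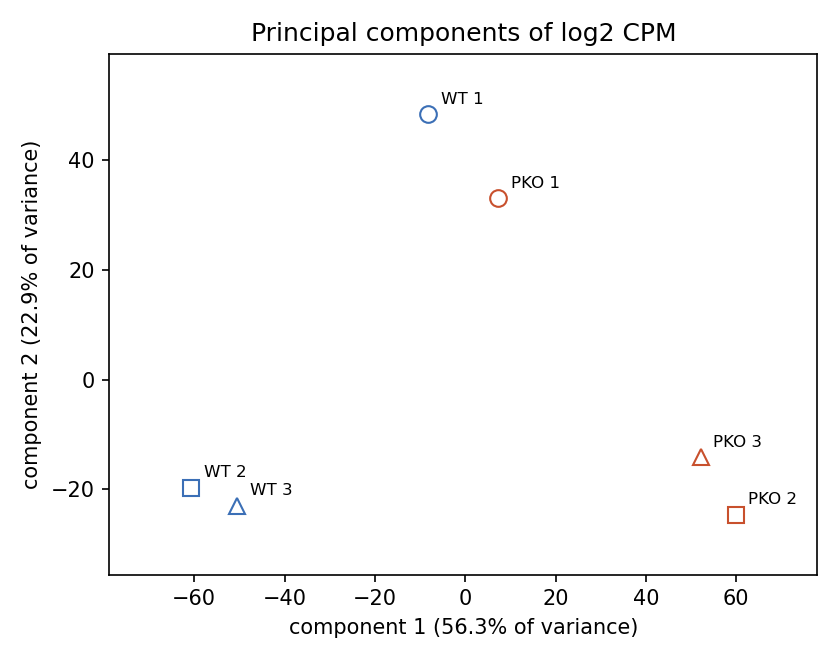
First and second principal components of log2 CPM over the 14025 genes tested, in arbitrary units of score, with WT libraries in blue and PKO libraries in red. WT 1 and PKO 1 have second-component scores of 48.4 and 33.1, and the other libraries lie between -24.6 and -14.1.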

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

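Of the tests in this part, sex as a term, the number 1 term, leaving out WT 1 and PKO 1 or PKO 2 and PKO 3, no robust fit and the DESeq2 counts under other designs were chosen after seeing the data; the alternatives for normalized values did not apply. Where a cause is not named, the cause was not tested. With edgeR the counts of genes higher and lower in PKO were 0 and 0, and stayed 0 with RLE or upper-quartile factors, library size only, no filter, a mean CPM of at least 1, limma-voom, no robust fit, sex as a term, and PKO 2 and PKO 3 left out. They were 766 and 151 (at least 2-fold, 646 and 83) with DESeq2, 1 and 0 (1 and 0) with the replicate block, 2 and 0 (2 and 0) with the number 1 term, and 1461 and 805 (1146 and 404) with WT 1 and PKO 1 left out. Leaving out 1 library at a time gave 0 to 659 higher and 0 to 483 lower (0 to 581 and 0 to 296). The DESeq2 counts of 766 and 151 ranged over 234 to 1434 and 13 to 918 when 1 library was left out. They were 318 and 49 with sex as a term, 1019 and 308 with the number 1 term, 1652 and 958 with WT 1 and PKO 1 left out, and 2 and 1 with PKO 2 and PKO 3 left out, where a single PKO library is assumed to vary like WT. Deviations from the group mean correlated across genes at 0.1, -0.03 and 0.13 within numbers 1 to 3. These low values do not exclude a batch shared by WT 1 and PKO 1, because each deviation also depends on the other libraries of its group. The log2 fold change of Pnpla2 kept its sign in every alternative, at -1.23 and past the threshold with DESeq2, at -1.20 and past it with WT 1 and PKO 1 left out, at -1.88 with PKO 2 and PKO 3 left out, and from -1.44 to -0.98 when 1 library was left out. Camera's 19 lists became 0 with an estimated correlation, 0 with fry and 11 with PKO 2 and PKO 3 left out; RLE factors, a mean CPM of at least 1, the replicate block and the number 1 term gave 19. Small differences changed direction. With PKO 2 and PKO 3 left out the log2 fold change was 0.000309 for mt-Nd4l, 0.25 for Myod1, 0.13 for Mymk (Tmem8c), 0.0789 for Des and 0.0214 for Cnp, and the opposite direction was given, with adjusted p, for fatty acid uptake (0.736), quiescence (0.454), commitment (0.533), p53 targets (0.736) and Schwann cell markers (0.906). Myod1 (0.009) and Schwann cell markers (0.812) reversed with sex as a term, Pdk4 (-0.28) and quiescence (0.991) with WT 1 and PKO 1 left out, and fatty acid uptake with fry (0.915) and a mean CPM of at least 1 (0.853). Over the libraries left out, Myod1 ran from -0.25 to 0.10, Mymk (Tmem8c) from -0.31 to 0.10 and Pdk4 from -0.40 to 0.53, and the adjusted p ran from 0.778 to 0.987 for fatty acid uptake, 0.473 to 0.991 for quiescence and 0.16 to 0.987 for Schwann cell markers. Of 94 named genes, all kept their direction and stayed short of edgeR's threshold under the other scalings, filters, block and number 1 term; 56 passed with DESeq2 and 67 with WT 1 and PKO 1 left out.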

Other observations

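All tests in this part were chosen after the results were seen. Taking the 10 genes with the highest and the 10 with the lowest fold change among DESeq2 calls whose groups did not overlap gave a set led by secreted and stress-related genes. Il6, a cytokine gene, was at 0.08 ± 0.03 CPM in WT and 7.11 ± 9.84 CPM in PKO (SD, n = 3 each; DESeq2 adjusted p = 0.00236, and 0.0594 without PKO 2, where the log2 fold change went from 6.49 to 4.21). Medag and Steap4, both known from fat cells, had no WT counts. Against a floor of 3 counts over the WT group, the pooled PKO level was at least 89.8-fold higher for Medag and 45.5-fold for Steap4. In PKO 1 to PKO 3 there were 8, 153 and 137 counts of Medag and 3, 108 and 40 of Steap4. These bounds therefore rest on PKO 2 and PKO 3 and do not hold for PKO 1 alone. With 1 library left out the bound ran from 57.3 to 131.5 for Medag, and from 18.9 without PKO 2 to 67.1 without PKO 1 for Steap4. Their DESeq2 adjusted p was 0.00133 and 0.000179. The Medag call ended without PKO 2 (0.177) or PKO 3 (0.184), and the Steap4 call without PKO 3 (0.296) or PKO 2, where DESeq2 gave no adjusted p. Prl2c2 (proliferin) was at 0.82 ± 0.42 and 136 ± 171 CPM (log2 7.35, and 5.56 without PKO 3), but it has near-identical family members that can share its reads. The lower genes included Reln (69.5 ± 37.0 and 21.3 ± 3.42 CPM), Ankrd2, a stretch-response gene of slow muscle (12.5 ± 6.49 and 3.16 ± 1.82 CPM), and Myo15b (20.8 ± 12.8 and 3.71 ± 1.45 CPM), with DESeq2 adjusted p of 0.00236, 0.0106 and 0.000548. In WT 1 these genes lay near PKO 1: Reln at 26.8 against 25.2 CPM, Ankrd2 at 5.08 against 4.95 CPM, and Myo15b at 6.14 against 4.42 CPM. Their differences rest mostly on WT 2 and WT 3.

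In some genes WT 1 stood nearer to PKO 1 than to WT 2 and WT 3. Cdkn2a, which encodes inhibitors of cell cycle entry, was at 111, 36.8 and 34.9 CPM in WT 1 to WT 3 and at 127, 130 and 170 CPM in PKO 1 to PKO 3. Nqo1, an NRF2 target, was at 41.7, 4.4 and 6.6 CPM in WT and at 36.8, 156 and 151 CPM in PKO. Neither passed edgeR (adjusted p = 0.268 and 0.248) or DESeq2 (0.0597 and 0.142) with all libraries.

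The real grouping was set beside the 9 other splits of the 6 libraries into 3 and 3. edgeR called 0 genes in the real split, a count that all 10 splits reached, and at most 2 in another. At an unadjusted p under 0.05 edgeR counted 2317 genes in the real split and 1690, 1642 and 1473 in the highest others. DESeq2 called 917 in the real split, reached in 1 of 10, and at most 342 in another. Camera called 19 lists, reached in 1 of 10, and at most 14 in another. With 10 splits a share under 0.05 cannot be reached. The DESeq2 splits next to the real one, with 321 to 342 genes each, set WT 2 and WT 3 with 1 PKO library against the rest.

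Stromal markers were high in PKO 2 and PKO 3: Pdgfra was at 102 and 95.2 CPM, Col1a1 at 857 and 249 CPM, and Dcn at 68.3 and 41.1 CPM, against at most 3.7, 17.1 and 2.4 CPM in WT. A single added population of one profile would keep its genes in one ratio between the libraries. The log2 ratio of the excess over WT in PKO 2 to that in PKO 3 ranged over 7.07, from -2.34 for Ly6a to 4.73 for Col15a1. The top value rests on a PKO 3 excess of only 3.4 CPM. Among genes with larger excesses Cd34 was at -1.21 and Smoc2 at 1.3, while Gsn (-0.21), Pdgfra (0.1) and Lox (0.79) lay nearer to each other. The range was weighed against counting error alone, so it speaks only against an identical profile. Stromal cells that came through the satellite cell sort and differed in state between the cultures, and a switch-on of these genes in the knockout myogenic cells, may both be at work and cannot be told apart: 14 of the 15 markers lay above every WT library in both, as either predicts. A lower share of myogenic cells also stays open. The stromal median exceeded the Schwann cell median by 3.41 on the log2 scale (95% bootstrap interval over genes 1.41 to 4.56). All 7 Schwann cell markers, however, had a WT mean of 1 CPM or more, a baseline that would hide a small share. Of the 15 markers 11 had a WT mean of 1 CPM or more, and 3 are held by another list. Among the PKO libraries, sex cannot be told apart from the difference in stromal marker levels. PKO 2 and PKO 3 had 17122 and 10007 counts of Xist, while PKO 1 had 3971 Y-linked counts. WT 3 had Xist counts too (20150), with a stromal list median of 0.23 relative to the WT mean.

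WT 1 and PKO 1 shared a profile: 42 genes were at least 2-fold above or below the other 4 libraries in both, against at most 6 in the other 8 pairs of a WT and a PKO library. They included Itga4 (46.2 and 44.0 CPM in WT 1 and PKO 1, at most 19.9 elsewhere), Rbfox1 (64.8 and 66.0, at most 29.5) and, in the other direction, Sema7a (18.7 and 21.7, at least 70.6 elsewhere). Exchanged labels are argued against by Pnpla2, which was 2.5 times as high in WT 1 as in PKO 1 (counting interval 2.07 to 3.01). Sex is argued against as the whole cause in these libraries. WT 2 carried Y-linked counts like WT 1, yet its correlation across genes was higher with WT 3 than with WT 1, by 0.028. That value was taken on log2 of CPM with 0.5 added, not on the log2 CPM with a prior count of 2. Its bootstrap interval, 0.026 to 0.03, resampled genes and covers no spread between libraries. A culture or library batch shared by the libraries numbered 1 remains possible and cannot be told apart from chance differences between cultures, because the labels give no batch and the 42 genes come from 1 library per genotype.

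Lower cell cycle transcripts in PKO might reflect slower proliferation or earlier exit in the knockout, which was not tested apart from other causes. Dilution by other cells would lower myogenic genes as much. The median of the commitment list, however, lay above that of the cell cycle list by 1.01 on the log2 scale. The 95% bootstrap interval of 0.76 to 1.13 resampled genes as if independent and covers no spread between libraries. The gap therefore describes these libraries and does not exclude dilution as a part of the difference. A difference in cycling between cultures that does not follow the genotype stays open, because WT 1, at -1.29 relative to the WT mean, lay below each PKO library. The difference rests on WT 2 and WT 3.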
